A study of Mus musculus with 3 samples.

How the data were processed

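RNA was measured in dental papillae, the mesenchymal core of the tooth germ that becomes the dental pulp, of ICR mice at embryonic days 16 and 18 (E16, E18) and at postnatal day 3 (P3). Per the labels' protocols, papillae were freed enzymatically from first molar germs of the lower jaw, each RNA sample pooled over 20 papillae, and biotin-labelled cRNA was made by 2-cycle labelling. Each stage has 1 array, so there are 3 arrays and no replicates. No test, standard error or p-value between stages is possible, and every statement compares 3 pooled samples, not 3 populations. The number of arrays limits the precision of every value.

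The deposited values are ratios for 45101 probe sets, of which 64 are controls, on an oligonucleotide array with Affymetrix probe set names. GCOS is named, without a version, per the submitters' processing notes; the scaling and centring steps are not given in the sources used here, and what follows about them was worked out from the values. In 40754 probe sets (90.4%) the middle of the 3 values was 1 within 1e-06, so each had been divided by its own middle value. In the other 4347, 99.98% of values lay within 0.01 of a whole number of steps of 1 size per array. Their highest middle value was 0.998, as when a middle scaled signal under 10 is replaced by 10 as the divisor. The step sizes gave 1 factor per array relative to P3, 0.7177 for E16 and 1.0802 for E18. Ratios between stages are therefore those of the scaled arrays, and centring does not alter them. The absolute level is lost, as is the cause of the scaling factors.

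The design had assumed deposited signals. Because the file holds ratios, a level was recovered for each probe set as the smallest number of steps, with 1 decimal per signal unit, that made all 3 signals whole within a relative 3e-07. The median solution was 1071 steps, against 18492 for ratios moved at random by about 1%. Solutions below a signal of 432.1, reached by 81.3% of centred probe sets, are rarely chance. A larger one may be chance, and any may be understated by a common factor, as in 17.2% of probe sets with known steps. The true level is never below the recovered one. Array medians were 82.1 (E16), 81.8 (E18) and 82.3 (P3). This recovery was chosen after the data were seen.

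The floor was the pooled median of the recovered signals, 82.1, and lower values were set to it before log2. The 81 values of bacterial control probe sets reached at most 70.2, with a median of 8.8. A gene entered a comparison when at least 1 of the 2 arrays was at or above the floor. With 1 side at the floor the difference is a bound, written "at least N-fold". Because levels can only be understated, such bounds are not inflated by the recovery.

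Gene names came from a table pairing probe sets with the platform annotation. It lists 35890 probe sets; 34958 have 1 symbol and 932 several, and 9160 probe sets of the file other than controls are not listed. No symbol changed when updated. The 18193 genes were each represented by the probe set with 1 symbol that had the highest mean recovered level, called the brightest here. Because recovered levels may be understated, it need not be the one with the highest true signal. No genome build is named, so no positions are given.

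Fixed before the data were examined were the 2-fold threshold, 26 gene lists (11 of them markers of cell types), the alternatives and the rule for named genes. Among genes measured on both arrays, that rule takes the 10 highest and 10 lowest at P3 against E16 and the 5 highest and 5 lowest of each step. It takes the 10 largest total changes among genes that moved 2-fold the same way at both steps and were at or above the floor on all 3 arrays. It also takes up to 6 members per list at least 2-fold different between P3 and E16, and the best known member. Other genes named are said to be chosen after their values were seen. A list's median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. This matching also used the recovered levels, with the same limit. A list stands apart when its percentile lies in the outer 2.5% on either side, which describes these arrays only.

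The spread between probe sets of the same gene is the only look at measurement error, and it misses errors that a whole sample or array shares. These differences, scaled to the error of 1 probe set, also gave the number of genes expected past 2-fold if all of that spread were error, an estimate added after the data were seen. On simulated data with an array SD of 0.25 on the log2 scale, levels were recovered exactly in 84.1% of 45036 probe sets, understated in 15.9% and overstated in 0.0%. The simulated levels were themselves built from the recovered signals. These shares therefore do not measure recovery for real probe sets whose recovered level is a chance solution. In the simulated P3 against E16 comparison, 44.0% of 100 genes changed 2-fold and 97.0% of 99 genes changed 4-fold passed the threshold, as did 0.41% of 11508 unchanged genes. Of 200 random lists, 6.5% stood apart. The simulated noise was a setting below the measured spread. Probe sets of one gene gave an SD of 0.60 for a P3 against E16 difference, with 4.6% past 2-fold in each direction. The 0.41% is thus not an error rate for these arrays.

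The alternatives were quantile normalization, scaling by the median of expressed probe sets, floors at the 25th and 75th percentiles, log2 of value plus floor, the mean over probe sets, leaving out probe sets that can detect several transcripts by their name ending, a 3-fold threshold, and unmatched random lists. An alternative added after the data were seen changed 3 choices together, using the deposited ratios without any floor, their mean over all centred probe sets of a gene, and unmatched random lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.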

Results

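Gene expression was compared in dental papillae of the mouse lower first molar at E16, before dentin forms, at E18 and at P3, with 1 array of pooled papillae per stage. The series title concerns genes down-regulated in papillae and pulp, so the comparisons ask which genes were lower, and which higher, at later stages. There were no replicates, and all differences are between single arrays. Over all probe sets the log2 signals correlated with r = 0.921 between E18 and E16, 0.89 between P3 and E16 and 0.926 between P3 and E18; probe sets are not independent replicates. Among spike-in controls added at hybridisation, the 18 probe sets read a median 2.17 times higher on the E18 than on the E16 array, and 1.04 times on the P3 array. The 3' over 5' ratio of actin, a sign of RNA and labelling quality, was 3.87 times as high on the E18 array and 2.46 times as high on the P3 array as on the E16 array, while that of Gapdh was 1.42 and 0.36 times.

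Between E16 and P3, the odontoblast and collagen lists were higher by their medians and the cell cycle list was lower. Dspp, which encodes the main non-collagenous dentin protein precursor, was at least 231-fold higher at P3 than at E16, and Phex, a regulator of mineralisation, at least 50.6-fold. The Phex value is that of its brightest probe set, 12.7-fold higher at P3 than at E18, where another probe set gave 1.44-fold. Dmp1, which encodes an acidic dentin matrix protein, was at least 9.53-fold higher and alkaline phosphatase (Alpl) 3.67-fold. Fibromodulin (Fmod) was 24.6-fold (9.94-fold to 33.2-fold by 4 other probe sets), decorin (Dcn) 15.0-fold and lysyl oxidase (Lox), which cross-links collagen, 8.31-fold higher. Mki67, a marker of dividing cells, was 3.36-fold lower, and the mitotic kinase gene Aurka 8.90-fold lower.

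Of 12199 genes measured, 796 (6.5%) were at least 2-fold higher at P3 than at E16 and 1878 (15.4%) lower; 194 of the former and 196 of the latter were bounds. The higher genes made up 29.8% of those past the threshold as deposited, but 49.0% after quantile normalization (1208 higher, 1259 lower) and 52.0% after median scaling (1247 higher, 1152 lower). Both of these bring the levels of the arrays together, so neither shows which split is right. The median of all genes was -0.17 as deposited, 0.02 after quantile normalization and 0.10 after median scaling. If all spread between probe sets of one gene were error, 565 genes would pass 2-fold in each direction.

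Among genes measured on both arrays, which leaves out bounds such as Dspp and Phex, the 10 largest positive differences were in Scin (32.0-fold higher at P3), Fmod, the macrophage mannose receptor Mrc1 (19.3-fold), clusterin (Clu, 16.6-fold), Dcn, tenascin C (Tnc, 14.5-fold), Dmkn (14.1-fold), the anion transporter Slc26a7 (13.7-fold), the sialyltransferase St8sia6 (13.7-fold) and Bmp2 (13.3-fold). With the same limit, the 10 largest negative differences were in Opcml (13.5-fold lower at P3), Rad54l (13.2-fold), the LIM-domain regulator Lmo1 (12.9-fold), the glycolytic enzyme gene Pfkl (10.9-fold), Col26a1 (10.6-fold), the antisense transcript Dlx1as (10.5-fold), the spindle checkpoint gene Bub1b (9.55-fold), the contactin gene Cntn3 (9.52-fold), Rrp8 (9.46-fold) and the activin subunit gene Inhba (9.42-fold). Other probe sets gave smaller decreases, 1.2-fold for Opcml, 2.60-fold for Cntn3, 6.89-fold and 1.18-fold for Pfkl, and 4.61-fold and 3.83-fold for Rad54l, and 2 others gave smaller increases for St8sia6 (6.74-fold and 6.79-fold).

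Of 17 measured genes of odontoblasts and mineralised matrix, 8 were at least 2-fold higher and 2 lower, with a median log2 difference of 0.54. Col24a1 (at least 8.12-fold) and the secretory kinase gene Fam20c (at least 3.57-fold) were among the higher ones. Of 27 collagens and collagen-processing genes, 11 were higher and 1 lower (median 0.79). Col1a2 was 6.31-fold (3.12-fold and 2.27-fold by 2 other probe sets), Sparc 6.67-fold (1.09-fold by 1 of 2 other probe sets) and Ogn 7.45-fold higher, and Col1a1 2.04-fold. The Col1a1 value is that of its brightest probe set. At P3 against E18 that probe set gave a log2 difference of 0.38, where another gave 5.38, so the size of the Col1a1 increase depends on the probe set. In the BMP and TGF-beta pathway, 7 of 24 genes were higher, among them Bmp2, the inhibitor Smad6 (6.20-fold) and Tgfb2 (4.79-fold), and 4 lower, among them Inhba and the activin antagonist gene Fst (3.84-fold), with a median of 0.34. All 3 lists stood apart from matched random lists, as they did under each of 9 alternatives.

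Of 33 cell cycle genes, 26 were at least 2-fold lower at P3 than at E16 and 0 higher, and the list's median was 3.36-fold lower, at percentile 0.0 of random lists. Mcm3, part of the replicative helicase, was 6.76-fold lower and Bub1 at least 5.58-fold. Rrm1, a ribonucleotide reductase subunit, was 5.80-fold lower by its brightest probe set but 1.38-fold and 1.15-fold by 2 others. Hypoxia and glycolysis genes had 7 of 23 lower and 0 higher, led by Pfkl, Ldha (5.31-fold), Slc2a3 (4.38-fold) and Pkm (4.29-fold), but their median of -0.43 did not stand apart.

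Transcription factors of dental mesenchyme went both ways, with 9 of 21 at least 2-fold lower and 3 higher, and the list did not stand apart (median -0.27, turning to 0.03 after quantile normalization, which moved the median of all genes from -0.17 to 0.02). Tfap2b was 8.0-fold, Lhx6 4.60-fold, Twist1 4.16-fold and Lhx8 3.48-fold lower at P3, while Dlx2 was 3.37-fold higher and Msx1 1.80-fold. Pax9 was 4.48-fold lower by its brightest probe set, but 2 others gave 1.85-fold lower and 1.04-fold higher. Aldh1a2, which makes retinoic acid, was at least 8.85-fold lower, and the retinoic acid carrier gene Crabp2 6.25-fold. In the Wnt pathway 10 of 26 genes were lower and 2 higher (median -0.56), among them the antagonists Dkk1 (5.80-fold) and Sostdc1 (4.26-fold, 2.47-fold by another probe set), the receptor Fzd1 (4.35-fold) and the feedback gene Axin2 (2.25-fold). The nerve growth and axon guidance list had 8 of 22 lower and 2 higher (median -0.64), with Nrp2 4.72-fold lower but 2.33-fold and 1.04-fold by 2 other probe sets. Hedgehog and FGF genes had 6 of 22 lower and 4 higher (median -0.47), including Dusp6, 4.40-fold lower, and Gas1, 4.93-fold higher but 1.71-fold by another probe set. None of these last 3 lists stood apart as deposited, but the Wnt list did under 6 of 9 alternatives and the nerve and axon list under 5.

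Markers of other cell types differed too. Of 20 macrophage and leukocyte markers 11 were at least 2-fold higher at P3 and 0 lower (median 1.19), including Mrc1, the complement gene C1qb (at least 8.0-fold), the chemokine receptor Cx3cr1 (at least 7.11-fold) and Pf4 (6.25-fold). Only 13 of the 24 markers on this list were at or above the floor at E16, and measured ones below it could not come out lower. The cartilage list had 5 of 11 higher and 0 lower (median 1.0). Only 3 of these 11 were at or above the floor at E16, so the others could not come out lower. The brightest of the 3 went opposite ways, with recovered signals from E16 to P3 of 1031 and 648 for Hapln1 and 173 and 522 for Sox9. Col2a1, below the floor at E16, was at least 1.09-fold higher, a bound that sets no upper limit. The macrophage and cartilage lists stood apart under every alternative. Of 8 erythroid markers 4 were lower (median -0.72), among them embryonic globin Hbb-y (at least 8.22-fold) and Alas2 (6.60-fold); this call was lost under 3 of 9 alternatives. The interferon response (median 0.38) and ribosomal protein (median 0.18) lists stood apart as deposited, and each lost that call under 2 of 9. Of 7 enamel genes, members of the epithelial list grouped after their values were seen and not set against random lists, 5 were at least 2-fold higher at P3. They were Amelx (at least 28.5-fold), Mmp20 (at least 28.9-fold), Enam (at least 11.4-fold), Ambn (6.51-fold) and Klk4 (at least 3.50-fold). Amtn differed little (1.19-fold), and Odam was at least 1.02-fold higher, which leaves the size of its difference unknown. Krt17 was at least 3.92-fold lower. The epithelial list had a median of 0.14 and did not stand apart as deposited, but did under 6 of 9 alternatives. Nor did markers of endothelium (-0.18), mural cells (-0.20), osteoclasts (-0.08), Schwann cells (0.44), neurons (0.37), skeletal muscle (0.19) and adipocytes (-0.20), or the lists of matrix remodelling (-0.06), retinoic acid (-0.15), imprinted growth genes (-0.08) and housekeeping genes (-0.46). Median scaling moved the median of all genes from -0.17 to 0.10, and those of 7 lists turned positive with it, at nearly unchanged distances from the median of all genes (0.10 and then 0.13 for matrix remodelling, -0.10 and then -0.09 for dental mesenchyme transcription factors). The other 5 were retinoic acid, imprinted genes, endothelium, mural cells and osteoclasts.

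**Figure D1:**
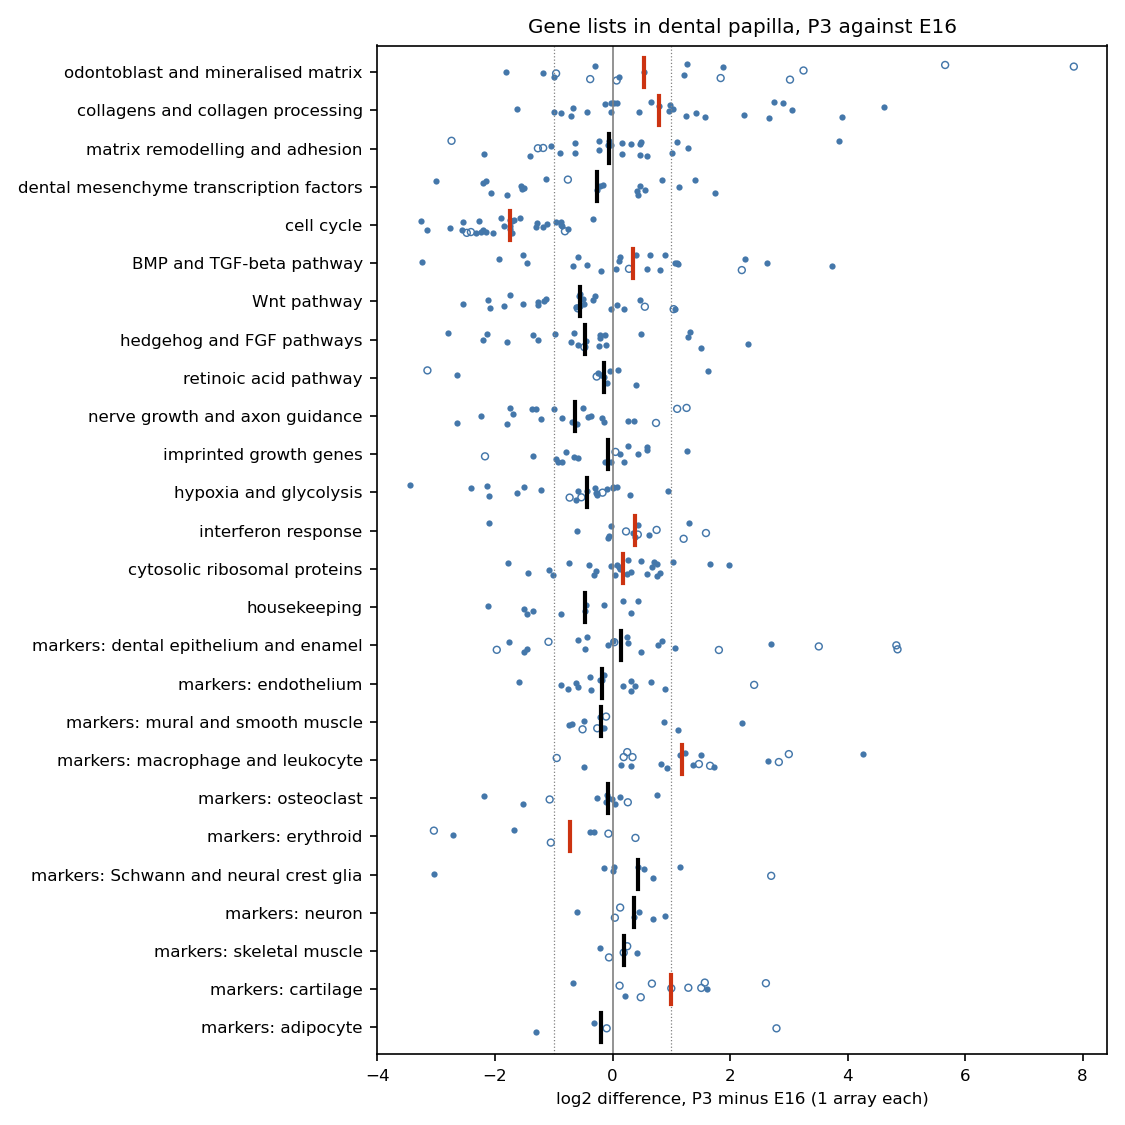
Log2 differences between P3 and E16 (x axis, log2 units, 1 array per stage) for the measured members of the 26 gene lists (y axis). Filled points were measured on both arrays and open points are bounds; bars are list medians, red where the list stood apart from matched random lists, with the cell cycle at -1.75 and collagens at 0.79.

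From E16 to E18, the dentin genes Dspp and Dmp1 and most epithelial markers were higher, and transcription factors of dental mesenchyme went both ways. Dspp was at least 49.7-fold and Dmp1 at least 45.3-fold higher at E18 than at E16. Bmp2, a growth factor of odontoblast differentiation, was 12.3-fold higher and Dlx2 8.47-fold. Inhba was 7.85-fold, Tfap2b 4.38-fold, Lhx6 4.45-fold and Twist1 4.37-fold lower, and Aldh1a2 was at least 8.85-fold lower. The dental mesenchyme list had 8 of 21 members at least 2-fold lower and 5 higher and did not stand apart (median -0.38). Of 33 cell cycle genes 2 were higher and 1 lower at 2-fold (median -0.02, or 0.08 after median scaling).

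Of 12040 genes, 962 were at least 2-fold higher and 961 lower at E18, a share higher of 50% that became 52.8% after quantile normalization and 60.5% after median scaling (1124 higher, 734 lower). The spread between probe sets alone would give 609 in each direction. Among genes measured on both arrays, which leaves out bounds such as Dspp and Dmp1, the highest 5 were Rpl27a (16.7-fold), Bmp2, Scin (10.9-fold), the selenophosphate synthetase gene Sephs2 (10.3-fold, against 2.40-fold and 1.63-fold by 2 other probe sets) and the chromatin organiser Satb1 (10.2-fold). With the same limit, the lowest 5 were AI606473 (9.06-fold), Tril (8.34-fold, against 2.65-fold by another probe set), the transcription cofactor Eya1 (8.08-fold), Egr2 (7.91-fold) and Opcml (7.86-fold). A total of 6 of 26 lists stood apart. Odontoblast genes had 8 of 17 higher and 2 lower (median 0.72). The Wnt list had 8 of 25 lower and 0 higher (median -0.57), with Fzd1 4.51-fold, the antagonist Frzb 3.98-fold and Axin2 2.02-fold lower; this call was lost when probe sets detecting several transcripts were left out. Ribosomal protein genes had 8 of 26 higher (median 0.76, falling to 0.18 and no longer apart under the same restriction).

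Most epithelial markers were higher at E18, with 14 of 21 at least 2-fold higher, 6 under 2-fold and 1 lower, and a median 2.33-fold higher. At or above the floor at E16 were 17 of the 26 on the list, and measured ones below it could not come out lower. Chosen after their values were seen, E-cadherin (Cdh1) was 4.0-fold, the basal epithelial regulator Trp63 4.51-fold, desmoplakin (Dsp) 3.63-fold and Krt5 2.33-fold higher, and Amelx was at least 6.88-fold and Ambn 3.91-fold higher. Macrophage markers had 5 of 18 higher and 1 lower (median 0.58), and cartilage markers 3 of 6 higher (median 0.97, not apart under 2 of 8 alternatives). Only 3 of these 6 cartilage markers were at or above the floor at E16, so the others could not come out lower.

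From E18 to P3, the cell cycle, glycolysis and epithelial lists were lower by their medians and the collagen list was higher. On the epithelial list 4 of 22 markers, all enamel genes, were at least 2-fold higher. Of 33 cell cycle genes 29 were at least 2-fold lower and 0 higher, with a median 3.39-fold lower. Bub1b was 9.11-fold (4.95-fold by another probe set) and Mki67 3.19-fold lower. Fmod was 25.4-fold (9.31-fold to 26.2-fold by 3 other probe sets), Lox 5.43-fold and Col1a2 5.70-fold higher, and Dspp 4.66-fold, while Dmp1 was 4.75-fold lower. Ldha was 6.06-fold and the glucose transporter gene Slc2a1 5.70-fold lower (3.46-fold by another probe set).

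Of 12117 genes, 490 were at least 2-fold higher and 1415 lower, a share higher of 25.7% that became 47.4% after quantile normalization (782 higher, 869 lower) and 43.5% after median scaling (743 higher, 967 lower). The spread between probe sets alone would give 386 in each direction. Among genes measured on both arrays, which leaves out bounds such as Enam, the highest 5 were the enamel protease gene Mmp20 (27.1-fold), Fmod, Phex (12.7-fold, against 1.44-fold by another probe set), Dmkn (11.5-fold) and Grb14 (9.69-fold). With the same limit, the lowest 5 were Jpt1 (11.4-fold, against 5.69-fold and 3.40-fold by 2 other probe sets), the tubulin gene Tubb2b (10.2-fold), the hyaluronan synthase gene Has3 (9.64-fold), Krtap17-1 (9.33-fold) and Dtl (9.18-fold, with log2 differences of -0.69 to -1.26 by 4 other probe sets). Collagens had 10 of 27 higher and 1 lower (median 0.58). The 2 measured Col1a1 probe sets gave log2 differences of 0.38 and 5.38. Hypoxia and glycolysis genes had 11 of 22 lower and 0 higher (median 2.11-fold lower). Collagen, cell cycle, glycolysis, epithelial and macrophage lists stood apart under all 9 alternatives.

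The epithelial list had 13 of 22 markers lower and 4 higher at P3 than at E18, a median 3.01-fold lower. Krt17 was at least 8.46-fold lower, and Krt5, Dsp and Trp63, again chosen after their values were seen, 6.41-fold, 5.43-fold and 4.50-fold. The 4 higher ones were enamel genes, Mmp20, Amelx (4.14-fold), Enam (at least 11.4-fold) and Klk4 (at least 3.50-fold), whereas Odam was 5.87-fold lower and Ambn (1.67-fold higher) and Amtn (1.15-fold) stayed under 2-fold. Macrophage markers had 6 of 19 higher and 0 lower (median 0.72). At or above the floor at E18 were 15 of the 24 on the list, and measured ones below it could not come out lower. The other 8 of the 13 lists that stood apart lost that call under at least 1 alternative. They were nerve growth and axon guidance (-0.63), odontoblasts (0.08), matrix remodelling (0.07), BMP and TGF-beta (0.16), interferon (0.43), endothelium (0.32), mural cells (0.16) and cartilage (0.63).

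**Figure D2:**
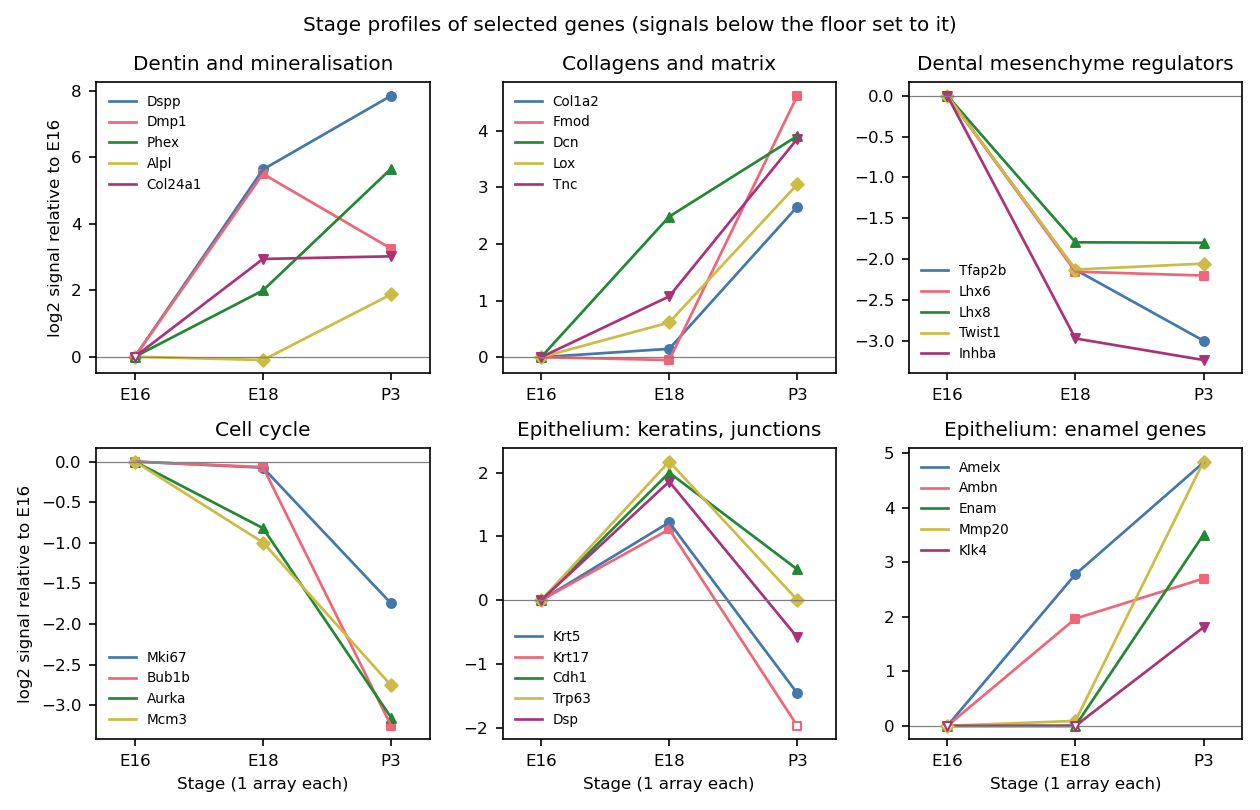
Log2 signal relative to E16 (y axis, log2 units) at E16, E18 and P3 (x axis, 1 array each) for genes chosen after their values were seen. The panel of dental mesenchyme regulators shows only genes lower at P3 than at E16, with Inhba from the BMP and TGF-beta list. On the dental mesenchyme list 9 of 21 genes were at least 2-fold lower and 3 higher. Each line is 1 gene by its brightest probe set, and open symbols are values below the floor, set to it; Dspp reaches 7.85 at P3, Mki67 -1.75, and Krt5 peaks at 1.22 at E18.

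Few genes moved the same way at both steps. Of 12553 genes, 44 were at least 2-fold lower at E18 than at E16 and again at P3 than at E18, and 38 were higher at both steps. Among those at or above the floor on all 3 arrays, the 10 largest total decreases were in Rad54l, Lmo1, Pfkl, Dlx1as, the replication genes Timeless (9.27-fold from E16 to P3, 4.53-fold by another probe set) and Cdc7 (8.31-fold), the collagen gene Col8a1 (8.21-fold, 5.34-fold by another), Thumpd1 (8.20-fold), the mitotic regulator Rcc2 (8.19-fold) and the phosphatase gene Dusp16 (7.73-fold). With the same limit, the 10 largest increases were in Scin, Mrc1, Clu, Dcn, Tnc, Slc26a7, Cgref1 (11.9-fold), the metabolic kinase gene Pdk4 (10.7-fold), the proteoglycan gene Bcan (10.6-fold) and Ccn4 (10.5-fold). Dspp and Phex, below the floor at E16 and so not ranked, also rose at least 2-fold at both steps. By other probe sets, log2 differences at 1 of the steps were under 2-fold for Rad54l (-0.31 and -0.76 from E16 to E18), Timeless (-0.43, from E16 to E18), Col8a1 (-0.88, from E18 to P3) and Clu (0.44 by 1 of 3, from E18 to P3), and at both steps for Pfkl by 1 of 2 (0.50 and -0.74). The first step of Bcan turned to -0.13 in the mean of the deposited ratios over all its centred probe sets, without a floor. In contrast, 365 genes were higher at E18 and then lower, and 90 lower and then higher. Both steps share the E18 array with opposite sign. Unchanged genes simulated with the spread between probe sets gave means of 0.8 lower at both, 0.7 higher at both, 119 higher then lower and 96.6 lower then higher, and independent steps would give 108, 37.6, 108 and 37.5. Part of the excess of genes highest at E18 may come from that shared array. For genes past 2-fold, other probe sets had the same sign in 79.4% of 1470 pairs at P3 against E16, 71.9% of 1045 at E18 against E16 and 79.5% of 1200 at P3 against E18.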

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

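Both results here concern data outside the comparisons of named genes. The 18 hybridisation spike-in probe sets, left out of the gene comparisons, read 2.17 times higher on the E18 than on the E16 array (range 1.68 to 4.43, higher in 18 of 18), and 0.45 times as high on the P3 as on the E18 array. Of 10092 probe sets without a single gene name, 4605 were measured at P3 or E16; 531 of them were at least 2-fold lower at P3 and 245 higher.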

How the results depend on the processing

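With 1 array per stage, no array could be left out and no sample labels exchanged. No paired analysis was possible because each stage has 1 sample. Of 99 recomputed counts 60 stayed within 1.5 times the reported one. Of 690 recomputed list medians 605 kept their side of the limit, without counting sign changes of lists that did not stand apart. Of 3598 differences of named genes 3271 moved by less than the spread between probe sets, whatever their sign, and 314 by more; 13 that were at least 2-fold as reported changed sign. Lists that stood apart under every alternative numbered 6 of 9 at P3 against E16, 3 of 6 at E18 against E16 and 5 of 13 at P3 against E18. Signal over background limits the comparisons, since genes under the floor on both arrays have no difference and weak genes give bounds. Where the alternative's own construction does not show it, the cause was not tested. In the values below, "higher" and "lower" count genes at least 2-fold apart unless stated, and medians are log2 differences.

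Quantile normalization gave 1208 higher at P3 against E16, and 782 higher and 869 lower at P3 against E18. At P3 against E16 the Wnt (-0.37), nerve and axon (-0.41) and epithelial (0.39) lists came to stand apart. The imprinted list (0.36) did so at P3 against E18, and the endothelial list (0.41) ceased to.

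Median scaling gave 1247 higher and 1152 lower at P3 against E16, 743 higher at P3 against E18 and 20 lower at both steps. The Schwann list (0.73, P3 against E16) gained its call and the mural list (0.33, P3 against E18) lost it.

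The floor at the 25th percentile gave 1354 higher at P3 against E16, 1030 higher at P3 against E18, 69 lower and 60 higher at both steps. Calls were gained at P3 against E16 by the Wnt (-0.56), epithelial (0.25) and skeletal muscle (-0.67) lists. At E18 against E16 the osteoclast (-0.46), neuron (0.42) and adipocyte (0.93) lists gained one. The imprinted list (0.01) gained a call at P3 against E18, and the mural list (0.02) lost one.

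The floor at the 75th percentile gave 413 higher and 1247 lower at P3 against E16, 597 higher and 562 lower at E18 against E16, 223 higher at P3 against E18, and 23 lower and 15 higher at both steps. The interferon median at P3 against E16 (-0.04) and the BMP and TGF-beta median at P3 against E18 (-0.02) reversed. Calls were gained by the Wnt (-0.87), nerve and axon (-1.03) and epithelial (0.15) lists at P3 against E16, and by the imprinted (-0.37), endothelial (-0.56) and erythroid (-1.11) lists at E18 against E16. The interferon (0.31), endothelial (0.12) and cartilage (0.07) lists lost theirs at P3 against E18.

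Adding the floor to every value, which shrinks differences of weak genes, gave 594 lower at E18 against E16, 324 higher at P3 against E18, and 15 lower and 20 higher at both steps. At P3 against E16 the epithelial list (0.16) gained a call and the erythroid list (-0.55) lost it. The osteoclast list (-0.48, E18 against E16) and the adipocyte list (-0.68, P3 against E18) gained one.

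The mean over probe sets gave 24 lower at both steps and 11 lists apart at E18 against E16. Calls were gained at P3 against E16 by the dental mesenchyme (-0.76), Wnt (-0.56), nerve and axon (-0.64) and epithelial (0.24) lists. At E18 against E16 they were gained by matrix remodelling (-0.40), dental mesenchyme (-0.44), BMP and TGF-beta (0.44), osteoclast (-0.57) and neuron (0.21) lists. At P3 against E18 the imprinted list (0.14) gained one, and the odontoblast (0.0), BMP and TGF-beta (0.03), nerve and axon (-0.29) and endothelial (0.14) lists lost theirs. Dtl reversed at E18 against E16 (-0.53).

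Leaving out probe sets that can detect several transcripts gave 24 higher at both steps. The ribosomal median at P3 against E16 (-0.12) and the odontoblast median at P3 against E18 (-0.30) reversed. At P3 against E16 the interferon (0.37) and erythroid (-0.19) lists lost their calls and the epithelial (0.25) and Schwann (0.56) lists gained one. At E18 against E16 the Wnt (-0.41), ribosomal (0.18) and cartilage (0.34) lists lost theirs, and the dental mesenchyme (-0.48) and interferon (-0.80) lists gained one. At P3 against E18 the matrix remodelling (0.07), endothelial (0.32) and mural (0.15) lists lost theirs. Genes then read by another probe set reversed, at P3 against E16 Rpl22 (0.63), Rps24 (-2.13) and Sema3f (0.02), at E18 against E16 Pfkl (0.50), Rps24 (-0.95), Sema3f (0.41) and Slc2a1 (-1.27), and at P3 against E18 Bpgm (0.02) and Ywhaz (0.03).

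A 3-fold threshold gave 306 higher and 636 lower at P3 against E16, 282 and 228 at E18 against E16, 149 and 400 at P3 against E18, and 0 lower and 8 higher at both steps. Random lists not matched on expression leave medians as they are. At P3 against E16 the Wnt (-0.56), nerve and axon (-0.64) and Schwann (0.44) lists then stood apart and the erythroid list (-0.72) did not. At E18 against E16 the dental mesenchyme (-0.38), BMP and TGF-beta (0.30) and glycolysis (0.31) lists stood apart. At P3 against E18 the ribosomal (-0.61) and housekeeping (-0.70) lists did, and the odontoblast (0.08), matrix remodelling (0.07) and mural (0.16) lists did not.

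An alternative chosen after seeing the data changed 3 choices together, taking the deposited ratios without a floor, their mean over all centred probe sets of a gene, and random lists not matched, so its values cannot be put down to the floor alone. It gave 1710 higher at P3 against E16, 1632 higher and 1634 lower at E18 against E16, 1461 higher at P3 against E18, and 71 lower and 83 higher at both steps. At P3 against E16 the Wnt (-0.55), hedgehog and FGF (-0.50), nerve and axon (-0.55) and Schwann (0.37) lists gained calls and the ribosomal list (0.13) lost it. At E18 against E16 the dental mesenchyme (-0.48), glycolysis (0.33) and osteoclast (-0.76) lists gained one and the cartilage list (0.35) lost it. At P3 against E18 the ribosomal list (-0.55) gained one, and the odontoblast (0.08), matrix remodelling (0.18), BMP and TGF-beta (0.02), endothelial (0.12) and mural (0.16) lists lost theirs. Bcan (-0.13) and Dtl (-0.53, the same as in the mean over probe sets with the floor) at E18 against E16 and Rps6 (0.06) at P3 against E16 reversed.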

Other observations

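The tests of cell mixture and array effects below were chosen after the patterns had been seen, as was the separation of enamel genes from other epithelial markers. The second lists were written before their own values were looked at; the tests of E18 scaling and of a lower share of papilla cells used values already seen. The bound for a second list was 1.5-fold.

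The 7 enamel genes and the other 19 epithelial markers parted between E18 and P3. Of the 7 measured enamel genes 4 were at least 2-fold higher at P3 than at E18 and 1 lower (median 3.50-fold higher), while of the 15 other markers measured 0 were higher and 12 lower (median 3.35-fold lower). From E16 to E18, 3 of 5 measured enamel genes were higher (median 3.91-fold) and 11 of 16 others (median 2.29-fold). Neither part was set against random lists. At P3 against E16 the enamel genes were a median 6.51-fold higher, and of the 15 others measured 5 were lower and 1 higher (median -0.44).

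The hyaluronan synthase genes went opposite ways between E16 and E18. Has2 was at least 6.70-fold lower at E18, whereas Has3 was 4.63-fold higher and then 9.64-fold lower at P3. Ctsk, a collagen-degrading protease gene, was 3.13-fold lower at E18 than at E16 and 5.26-fold higher at P3 than at E18, and Igf2 was 1.74-fold lower at E18 and 1.71-fold higher afterwards. The mural cell gene Rgs5 was 6.03-fold higher at E18 than at E16 by its brightest probe set and 2.19-fold by another, while the mural list's median was -0.29.

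Most epithelial markers were higher at E18 than at E16. At P3 against E18, 12 of the 15 measured markers other than enamel genes were at least 2-fold lower and 0 higher. Of 7 enamel genes, 4 were higher and 1 lower. A different scaling of the E18 array is argued against, since the first list's median was still 1.42 after quantile normalization. Epithelium carried over into the E18 sample is a candidate explanation, because a second list of epithelial genes had a median of 0.65 over 28 measured genes, 24 of them above 0, and one of -0.93 between P3 and E18. Second-list members below the floor at E16, such as Jup, Pof1b and Ocln, could only come out above 0 at E18, so their signs carry no weight. The levels of markers on the first list were substantial at every stage, with recovered signals of at least 2069 for Krt5 at E16, 4821 for Krt5 at E18 and 5377 for the enamel gene Ambn at P3. At or above the floor were 17 of 26 markers at E16, 20 at E18 and 20 at P3. Developmental regulation within the dissected tissue stays open and untested, and the enzymatic dissection is meant to remove this tissue.

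Cell cycle genes were lower at P3 than at either embryonic stage. Compression of bright probe sets on the P3 array is argued against by a second cell cycle list, whose median after quantile normalization was -1.39 relative to matched random lists. Loss of epithelium alone is argued against because that list was at -1.64 between P3 and E16, with 37 of 47 genes at least 2-fold lower, while the second epithelial list was at -0.13 and the markers other than enamel genes at -0.44; loss of some epithelium is not excluded. Fewer dividing cells in older papillae may account for the difference, as a hypothesis that 1 sample per stage leaves untested; a change in other cell types than those listed also stays open.

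Macrophage markers were higher at P3 than at E16 (median 1.19), and so were markers of cartilage (1.0), Schwann cells (0.44) and neurons (0.37), of which only cartilage stood apart. Only 3 of the 11 measured cartilage markers were at or above the floor at E16, so the others could not come out lower. A lower share of papilla cells as the whole cause, which would raise all other cell types alike, is argued against by endothelial (-0.18), mural (-0.20) and erythroid (-0.72) markers, the last between -1.52 and -0.19 over the alternatives with the call lost under 3 of 9; a part in the change is not excluded. More leukocyte RNA in the P3 sample may account for the macrophage difference. A second macrophage list, however, had a median of 0.49, under the 1.5-fold bound set for it, although 19 of 20 genes were above 0 and its percentile was 99.94. Members below the floor at E16, such as Apoe, Lyve1 and Ly86, could only come out above 0, so their signs carry no weight. After quantile normalization, which also moved the median of all genes from -0.17 to 0.02, the second list's median was 0.71, above the 1.5-fold bound. All 20 of 20 genes were then above 0, with the same limit on weak members, so the outcome depends on the scaling. Whatever its outcome, the test could not tell more cells from a higher level per cell, since either would raise these genes in pooled RNA.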
